A study of Mus musculus with 17 samples.

How the data were processed

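The series holds polyA RNA sequencing of mouse cerebral cortex, in 17 libraries of 8 groups: 7 purified cell types with 2 libraries each and whole cortex with 3. Groups were taken from the sample labels, which give no ages, sort markers or animal numbers. The values are FPKM made by the authors and deposited per gene symbol and per RefSeq isoform, with values under 0.1 listed as 0.1. Per the submitters' processing notes the build was mm9 and the tools were CASAVA, TopHat 1.3.3, Bowtie 0.12.7 and Cufflinks 1.3.0. The files held 22462 genes and 28408 isoforms, of which 1 isoform was left out. The gene value equalled the sum of its isoforms within 0.0001 FPKM for 98.4% of values.

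Whether whole reads could be recovered from the FPKM was checked by counting genes that share a ratio between libraries. At most 10 genes of 2344 to 3306 fell in a ratio window, against 7 after shuffling, so reads were not recovered and the depth per library is unknown. No counting intervals are given, and low values carry an unknown counting error. No coordinates are given, since the reference at hand is of another build.

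Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), in a single cell-means model of the 8 groups with a trended prior variance. Groups of 2 libraries thereby share an estimate of the spread. Genes needed at least 1 FPKM in at least 2 libraries, which left 14011. A gene was called higher in a type when the largest of its one-sided p-values against each other type, adjusted by Benjamini-Hochberg, was under 0.05 and its log2 difference from the nearest type was at least 1. Whole cortex was tested the same way against the 7 types, in both directions. The steps between oligodendrocyte stages and astrocytes against neurons used two-sided tests with the same limits. Isoform use was tested with diffSplice of limma and Simes' method, for genes with a sum of at least 5 FPKM and isoforms with a share of at least 5%, and called at a share difference of at least 20 points.

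Gene lists were written before the data were examined: 8 marker lists of the cell types, 6 lists of other cells and 18 lists of functions, 32 in all. Each was tested in 12 contrasts with camera of limma, with a preset correlation of 0.01 and again with the estimated correlation, and the 384 tests were adjusted as a family. Members were also adjusted over the list alone, and those counts are given where they differ from the counts over all genes. In the contrasts of a type the list tests use the mean of the other purified types.

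The genes named follow a rule fixed at the same time. For each type these are its marker list and the 10 called genes with the largest log2 difference from the next-highest type, with both libraries above every library of the other purified types. Symbols ending in Rik or made of Gm or LOC and digits were passed over there. The lineage follows the same rule, each step and astrocytes against neurons name the 8 largest rises and 8 largest falls, and whole cortex names 10 genes per side. For each function list up to 4 members with the largest absolute log2 difference are named. For isoforms a fixed list and the 10 largest share differences are named. Genes of other cells beside a comparison, members of lists that were called in another type, and genes of the closing section were named after their values were seen. A few genes that the rule names are not reported here.

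The tests were tried on simulated data with known changes, in 66 or 67 genes for each size of change in each gene comparison. Changes of 4-fold were recovered for 89.6% to 97.0% of genes and changes of 8-fold for 96.97% to 100% in each comparison. Changes of 2-fold, which lie at the limit of the log2 difference, were recovered for 4.48% to 47.8%. At most 4 unchanged genes were called in a comparison. For isoforms a change of 30 points was recovered in 92% of 100 genes and a change of 60 points in 97% of 100, with 3 unchanged genes called. The changes were placed in genes of higher mean level, in data with no other differences between groups. Simulated isoform genes lay well above the limit of the isoform test and had 2 isoforms each. The simulated noise of a gene had the same spread in every group and was independent between libraries. Recovery and false calls for low genes and for genes with more isoforms were therefore not measured. Nor were they measured where the spread differs between groups or libraries share a difference.

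Alternatives tried were a pseudocount of 0.1, no filter and a filter at 5 FPKM, median-of-ratios scaling, scaling to a common sum of FPKM, a replicate block, a constant prior variance, a log2 difference of at least 2, only the 2 groups compared in the fit, and each library left out. For isoforms the gene sum and the share difference were varied, and for lists the correlation and the pseudocount. Figures and tables of values were made with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.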

Results

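Polyadenylated RNA was sequenced from 17 mouse cerebral cortex libraries. They fall into 7 purified cell types with 2 libraries each, namely astrocytes, neurons, oligodendrocyte precursor cells, newly formed oligodendrocytes, myelinating oligodendrocytes, microglia and endothelial cells, and 3 libraries of unsorted whole cortex. Astrocytes are the glia that take up transmitter and line vessels, oligodendrocytes form myelin, microglia are the resident macrophages of the brain, and endothelial cells line its vessels. Levels are FPKM as deposited, a read density scaled to transcript length and library size, for 22462 genes and 28407 isoforms, and every gene has a floor of 0.1 FPKM. The number of reads per library is unknown, so no counting interval is given. The sum of FPKM ran from 205621 to 389838 per library, and 30.8% to 45.1% of genes stood at the floor. Levels below are mean ± SD over n = 2 libraries per purified type and n = 3 for whole cortex. A log2 difference is on the log2(FPKM + 1) scale, which understates changes of low genes, and the adjusted p is that of limma. The labels do not say that libraries of a type came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

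The purity of the cell types was read from marker lists. Among the purified types each list had its highest median in its own type, with overlap between neighbouring oligodendrocyte stages. Precursor markers had a median of 26.7% and 22.9% of the precursor level in the newly formed libraries, newly formed markers 29.02% and 25.97% of their own level in the precursor libraries, and myelinating markers 40.7% and 27.4% in the newly formed libraries. Astrocyte markers such as Aqp4, the water channel of astrocyte endfeet, had a median of 0.438% to 11.3% of their astrocyte level in the other purified libraries, highest in precursor replicate 1. Neuron markers such as Syt1, a calcium sensor of vesicle release, reached 14.04% and 12.995% of the neuron level in the precursor libraries and 8.43% in myelinating replicate 2. Microglia markers such as Csf1r, the receptor for colony stimulating factor, stood at 4.55% and 2.69% of the microglia level in the precursor libraries and under 1% in the other purified types. Endothelial markers such as Cldn5, a tight junction protein, reached at most 0.676% of the endothelial level elsewhere among the purified types. Markers of myelinating cells such as Mog were at 0.356% to 0.551% of the myelinating level in whole cortex, where neuron markers stood at 92.6% to 93.7% of the neuron level. Hemoglobin transcripts varied between libraries of a type. Beta-s, an adult globin chain whose reads may be shared with its paralogs, was listed at 13344 FPKM in precursor replicate 1, which is 5.54% of that library's sum, against 7149 ± 8761 FPKM over both precursor libraries. Libraries of a group correlated at r = 0.977 to 0.998 across genes, lowest for the precursors, where genes are not independent replicates.

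**Figure D1:**
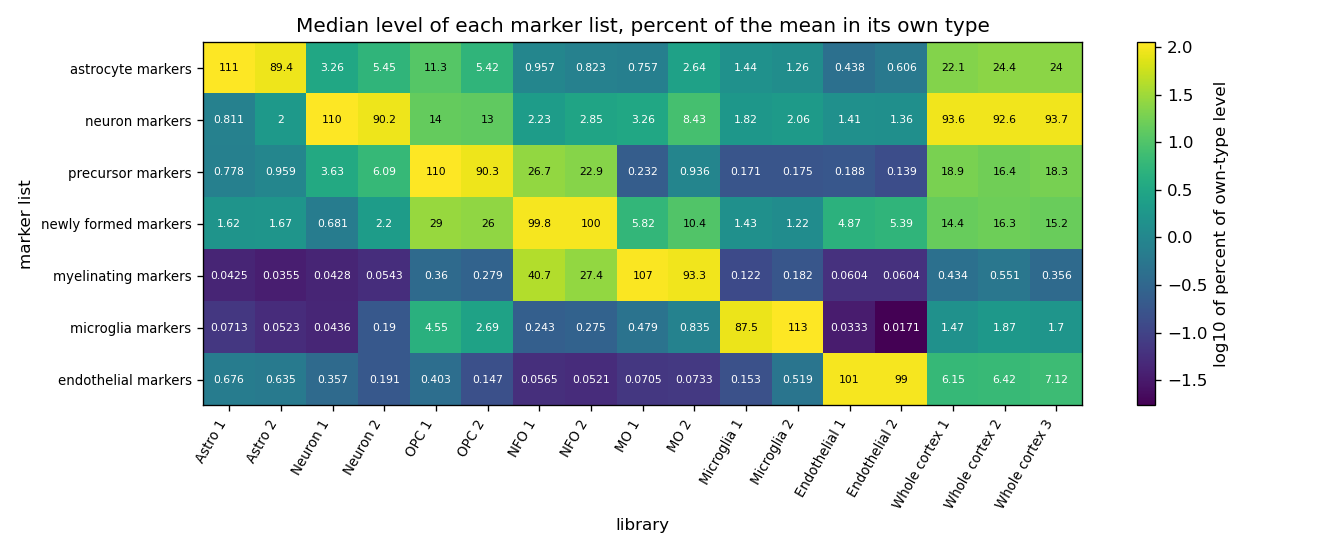
Median level of each of 7 marker lists (vertical axis) in each of the 17 libraries (horizontal axis), as a percent of the mean level in the list's own cell type, with colour on a log10 scale and the percent printed in each cell. Each list is highest in its own type among the purified types, and neuron markers stand at 14.04% and 12.995% in the precursor libraries.

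How many genes mark each type was asked by requiring a gene to be higher in a type than in each of the other 6 purified types, with a log2 difference of at least 1 from the next. Of 14011 genes tested, microglia had 985, endothelial cells 881, neurons 799, astrocytes 513, precursors 209, myelinating oligodendrocytes 98 and newly formed oligodendrocytes 64. The mean of the 3 oligodendrocyte stages gave 312 genes higher than in each of the other 4 types. The order of the types depended on the scaling. With libraries brought to a common sum of FPKM, neurons had 1054 genes, endothelial cells 752 and microglia 720. Newly formed cells then had 68 and myelinating cells 58. Median-of-ratios scaling kept microglia highest at 1216 and newly formed cells lowest at 42.

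**Figure D2:**
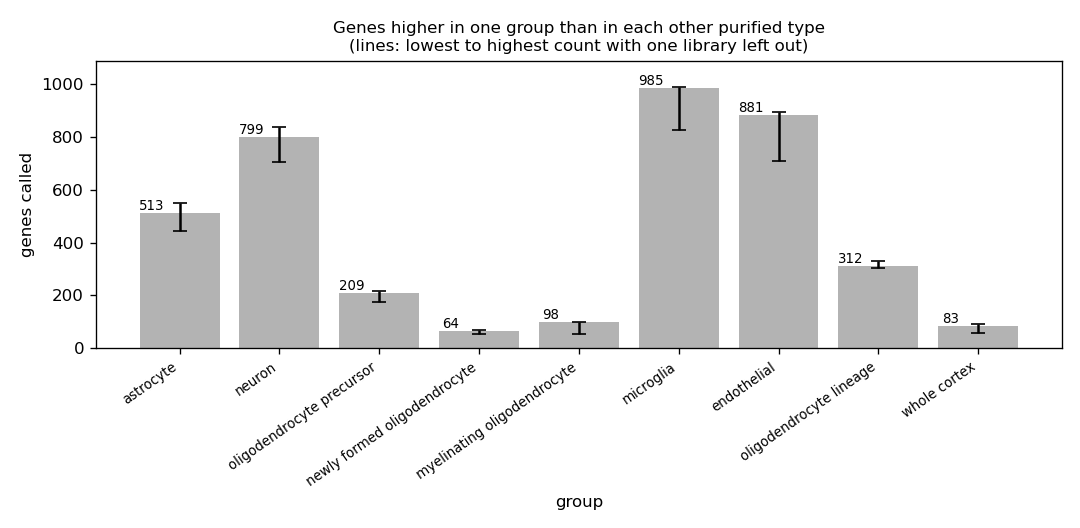
Number of genes (vertical axis, from 0) higher in each purified type, in the oligodendrocyte lineage or in whole cortex (horizontal axis) than in each other purified type, with lines from the lowest to the highest count when a library is left out. With FPKM as deposited, microglia have the most genes, 985, and newly formed oligodendrocytes the fewest, 64. Both ends of this order changed with libraries brought to a common sum of FPKM. The count for myelinating oligodendrocytes fell to 56 without replicate 1 of that type.

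Astrocytes were marked by Aqp4, at 319 ± 21.1 FPKM against 11.8 ± 7.83 in neurons, the next type (log2 difference 4.79, SE 0.46, adjusted p = 3.16e-06). Aldh1l1, a folate enzyme, was at 144 ± 3.82 against 7.96 ± 4.37 FPKM in neurons (log2 difference 4.11, SE 0.34, adjusted p = 7.52e-07). Slc6a11, a GABA transporter, stood at 557 ± 77.2 FPKM and Fgfr3, a growth factor receptor, at 293 ± 58.9 FPKM, with log2 differences of 3.97 and 3.94 from the next type. Of the 12 astrocyte markers 11 were higher in astrocytes than in each other type, and 12 when adjusted over the list alone. The exception was Gjb6, a gap junction protein, at 53.1 ± 31.9 FPKM in astrocytes and 17.03 ± 10.02 in precursors (log2 difference 1.57, SE 0.51, adjusted p = 0.0703). The list as a whole was higher in astrocytes than other genes were (camera adjusted p = 3.24e-07, and adjusted p = 0.321 with an estimated correlation). Besides Aqp4, Aldh1l1, Slc6a11 and Fgfr3, the 10 genes with the largest difference held Ppp1r3c, a glycogen-targeting phosphatase subunit, at 105 ± 10.02 FPKM (log2 difference 4.69, SE 0.30, adjusted p = 5.96e-08). Grm3, a metabotropic glutamate receptor, was at 158 ± 30.2, Hgf, a growth factor, at 28.4 ± 1.25, Itih3 at 68.4 ± 6.65 and Cbs, the enzyme that makes cystathionine, at 90.4 ± 5.83 FPKM. With Slc4a4, a bicarbonate cotransporter, their log2 differences ran from 3.98 to 4.35. Gfap, the glial filament protein, was at 126 ± 27.8 FPKM with myelinating oligodendrocytes next at 18.3 ± 0.369 FPKM, and Sox9, a transcription factor, at 92.6 ± 14.3 FPKM (log2 difference 3.33, SE 0.18, adjusted p = 1.25e-08). Slc1a3 and Gja1, a glutamate transporter and a gap junction protein, differed from the next type by 2.87 and 2.93 on the log2 scale.

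Of 12 target genes of Notch and Wnt signalling, 8 were higher and 0 lower in astrocytes than in the mean of the other purified types, with the same counts adjusted over the list alone (camera adjusted p = 8.84e-04, and adjusted p = 0.366 with an estimated correlation). Hes5 was at 289 ± 10.9 FPKM against 72.1 ± 3.40 in precursors, Nrarp at 119.6 ± 13.1, Hey2 at 14.3 ± 0.473 and Hes1 at 129.8 ± 6.81 FPKM, the last close to the endothelial level of 107 ± 4.26. Lists fixed for other functions also had members highest in astrocytes: Idi1, Sc4mol and Tm7sf2 of cholesterol synthesis, Gabra4, Gabrb1, Gabrg1, Grm3 and Grm5 among transmitter receptors, Axl, Megf10 and Mfge8 among phagocytosis genes, and Hapln1, Lama2, Ncan and Tnc of the matrix. Fos and Nr4a1, immediate-early genes, were also highest in astrocytes, and Notch3 of the mural cell markers stood at 32.6 and 35.6 FPKM in the astrocyte libraries. Precursors were the next-highest type for 49.5% of the 513 astrocyte genes, the purified type whose libraries held the most astrocyte marker RNA after astrocytes. The calls of Slc1a2, Aldoc and Atp1b2 were lost with no filter on low values, without astrocyte replicate 1 or without precursor replicate 2, where the log2 difference of Aldoc was 0.91, and Gjb6 was called after either rescaling of the libraries or without some single libraries. At a log2 difference of at least 2 the count was 159.

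Neurons were marked most by Reln, a secreted glycoprotein of Cajal-Retzius cells and interneurons, at 847 ± 572 FPKM against 1.23 ± 0.383 in astrocytes (log2 difference 8.40, SE 0.33, adjusted p = 9.53e-11). Sst, the peptide somatostatin, was at 706 ± 139.8 FPKM (log2 difference 7.22, SE 0.44, adjusted p = 1.23e-08). Npy, neuropeptide Y, was at 646 ± 54.9 FPKM (log2 difference 5.51, SE 0.42, adjusted p = 1.26e-07). Slc17a6, a vesicular glutamate transporter, stood at 62.3 ± 16.6 FPKM (log2 difference 5.74, SE 0.16, adjusted p = 3.23e-12). Dlx1, a transcription factor of interneurons, was at 60.4 ± 19.2 FPKM, and Nhlh2 and Trp73, transcription factors, at 66.9 ± 1.91 and 72.8 ± 5.83 FPKM with log2 differences of 5.94 and 5.93. The remaining genes of the 10 largest differences were Snhg11, Islr2 and Nxph4, from 5.01 to 6.47. Of the 12 neuron markers 8 were higher in neurons than in each other type, also adjusted over the list alone (camera adjusted p = 2.30e-05, and adjusted p = 0.329 with an estimated correlation). Tubb3, a tubulin, was at 331 ± 59.02 FPKM (log2 difference 4.35, SE 0.43, adjusted p = 2.24e-06). Stmn2 was at 388 ± 107, Syt1 at 123 ± 9.47, Snap25 at 148 ± 43.9, Gad1, which makes GABA, at 66.9 ± 11.98, and Rbfox3, a splicing factor, at 18.1 ± 1.78 FPKM.

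The 4 other neuron markers did not differ upward from the next type. Slc17a7, the glutamate transporter of cortical projection neurons, was at 15.2 ± 7.38 FPKM in neurons, 23.5 ± 11.2 in microglia and 96.8 ± 10.1 in whole cortex. Mtap2, a dendrite protein, was at 84.6 ± 41.8 FPKM in neurons and 80.1 ± 21.9 in precursors (log2 difference 0.01, SE 0.36, adjusted p = 1), and its difference turned negative without neuron replicate 2 or precursor replicate 2. The neurofilament genes Nefl and Nefm were at 6.26 ± 3.95 and 1.61 ± 0.358 FPKM in neurons, with log2 differences of 0.61 and -0.30 from precursors. All 4 had their highest mean in whole cortex. The neuron libraries therefore need not stand for all neurons of the cortex, here or in the comparisons with astrocytes.

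Of 19 synaptic vesicle genes 19 were higher in neurons than in the mean of the other types, and 15 higher than in each of them (camera adjusted p = 3.04e-08, and adjusted p = 0.326 with an estimated correlation). Syt4 and Syp, vesicle proteins, were at 82.2 ± 16.8 and 252 ± 31.7 FPKM. Of 31 transmitter receptor genes tested 25 were higher against the mean (camera adjusted p = 1.56e-08, and adjusted p = 0.329 with an estimated correlation), among them Grm2 at 36.7 ± 1.19, Gria1 at 52.6 ± 10.8 and Grin1 at 63.5 ± 0.707 FPKM, and 7 were higher than in each other type. Of 12 interneuron genes 11 were higher by either test, Calb2, a calcium buffer, at 109.9 ± 23.8 FPKM among them (camera adjusted p = 1.41e-06, and adjusted p = 0.313 with an estimated correlation). Of 12 genes of glutamatergic neurons and cortical layers 7 were higher against the mean, 8 adjusted over the list alone, with Tbr1 at 42.1 ± 1.07, Bcl11b at 6.65 ± 2.26 and Neurod2 at 6.61 ± 0.859 FPKM (camera adjusted p = 3.66e-04, and adjusted p = 0.242 with an estimated correlation). Precursors, which held neuron marker RNA at 14.04% and 12.995%, were next-highest for 57.9% of the 799 genes. The count was 268 at a log2 difference of at least 2.

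Oligodendrocyte precursor cells were marked by Pdgfra, the receptor for platelet-derived growth factor, at 595 ± 45.7 FPKM against 79.4 ± 13.6 in newly formed oligodendrocytes (log2 difference 2.90, SE 0.45, adjusted p = 8.59e-04). Cspg4, the NG2 proteoglycan, was at 116 ± 21.7 against 22.9 ± 3.06 FPKM (log2 difference 2.28, SE 0.18, adjusted p = 2.42e-06). Lhfpl3, Pcdh15, C1ql1, Xylt1 and Emid1 were also higher, with log2 differences from 1.65 to 2.24. Of the 10 precursor markers 7 passed, the same number adjusted over the list alone (camera adjusted p = 1.43e-07, and adjusted p = 0.242 with an estimated correlation). The others were Ptprz1, at 1022 ± 51.5 FPKM in astrocytes and 418 ± 182 in precursors, Vcan (log2 difference 0.86, SE 0.42, adjusted p = 0.603), and Tnr at 111 ± 78.7 FPKM in precursors and 158 ± 97.8 in newly formed oligodendrocytes, a difference whose sign turned without precursor replicate 2 or newly formed replicate 1. Of the 10 genes with the largest difference, Mmp15, a membrane metalloproteinase, was at 246 ± 92.5 FPKM (log2 difference 2.69, SE 0.22, adjusted p = 2.42e-06). Cdo1, a cysteine dioxygenase, was at 193 ± 49.1 FPKM, Lnx1 at 58.1 ± 11.5, Fam70b at 97.8 ± 33.2 and C1ql2 at 14.2 ± 5.22 FPKM.

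The remaining 4 of those 10 genes, Dcn, Lum, Col3a1 and Slc6a13, are on the fibroblast marker list. Dcn and Lum, small matrix proteoglycans, were at 29.5 ± 7.49 and 10.3 ± 1.51 FPKM in precursors (log2 difference 3.80, SE 0.20, adjusted p = 1.08e-07, and log2 difference 3.26, SE 0.11, adjusted p = 4.90e-10). Col3a1, a fibrillar collagen, was at 23.2 ± 10.3 FPKM. Of 8 fibroblast markers 6 were higher in precursors than in each other purified type, and 7 adjusted over the list alone. They were also present in whole cortex, where Dcn stood at 9.42 ± 0.314 FPKM. Of 20 extracellular matrix genes 10 were higher and 2 lower in precursors than in the mean of the other types, which did not set the list apart (camera adjusted p = 0.142, and adjusted p = 0.618 with an estimated correlation). Vcan, Tnr, Bcan and Acan, parts of the neural matrix, had the largest differences, from 2.60 to 4.48 against the mean, and Acan alone of the list was higher than in each other type. Hemoglobin RNA moved with this group through replicate 1, where Hbb-b1 was at 1931 FPKM against 157 in replicate 2, and 0 of 3 erythroid markers were called in any type. The 209 precursor genes became 134 after median-of-ratios scaling and 33 at a log2 difference of at least 2.

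Newly formed oligodendrocytes were marked by Fyn, a tyrosine kinase, at 446 ± 74.7 FPKM against 80.7 ± 6.71 in precursors (log2 difference 2.44, SE 0.18, adjusted p = 1.82e-06). Enpp6, a choline phosphodiesterase, was at 182 ± 44.4 against 48.6 ± 13.2 FPKM in myelinating cells (log2 difference 1.89, SE 0.21, adjusted p = 1.26e-04). Bmp4, a secreted growth factor, was at 37.1 ± 4.80 against 10.5 ± 1.22 FPKM in precursors (log2 difference 1.73, SE 0.21, adjusted p = 3.02e-04). Epcam, an adhesion molecule, was at 11.5 ± 2.45 FPKM (log2 difference 2.92, SE 0.14, adjusted p = 4.13e-08). Casr, the calcium-sensing receptor, was at 15.4 ± 3.04 against 2.14 ± 0.516 FPKM in myelinating cells. The other genes of the 10 largest differences were Gp1bb, Tmem108, Matn1, Ust, Col9a3, Mical3 and Kif19a, with log2 differences from 2.08 to 2.63. Of the 10 markers of this stage 6 passed, 7 adjusted over the list alone (camera adjusted p = 2.07e-10, and adjusted p = 0.112 with an estimated correlation), Rap2a, Mycl1 and Itpr2 among them. Gpr17, a receptor of this stage, was at 925 ± 124 FPKM and 438 ± 59.4 in precursors (log2 difference 1.08, SE 0.29, adjusted p = 0.116). Bcas1 was at 529 ± 103.4 and 415 ± 87.97 in myelinating cells, Neu4 at 92.3 ± 18.5 and 99.3 ± 10.6 in precursors, and Tcf7l2 at 13.96 ± 6.04 FPKM, none of which passed. Median-of-ratios scaling turned the sign for Bcas1 and Neu4, called Gpr17, which was also called without either neuron library, and lost Rap2a, and the call of Itpr2 (log2 difference 1.23, SE 0.29, adjusted p = 0.0473) was lost under most alternatives. That of Mycl1 was lost with no filter, without neuron replicate 2, without precursor replicate 1 and without newly formed replicate 2. The 64 genes became 42 after median-of-ratios scaling and 12 at a log2 difference of at least 2.

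Myelinating oligodendrocytes were marked by Gjb1, a gap junction protein, at 179 ± 3.98 FPKM against 33.96 ± 0.269 in newly formed cells (log2 difference 2.37, SE 0.19, adjusted p = 6.97e-06). Mog, a myelin surface protein, was at 1711 ± 112 against 508 ± 59.1 FPKM (log2 difference 1.75, SE 0.25, adjusted p = 9.53e-04). Klk6, a protease, was at 19.6 ± 2.18 against 4.12 ± 0.809 FPKM (log2 difference 2.02, SE 0.11, adjusted p = 4.22e-07). Mbp, myelin basic protein, reached 94425 ± 27907 FPKM against 26458 ± 1475 in newly formed cells (log2 difference 1.80, SE 0.33, adjusted p = 0.00757), and it made up 34.8% and 25.1% of the sum of FPKM in the 2 myelinating libraries. Of the 12 markers 7 passed, 9 adjusted over the list alone (camera adjusted p = 1.35e-22, and adjusted p = 0.0654 with an estimated correlation), with Mal, Opalin, Aspa and Apod completing the 7. Mag was at 1995 ± 162 FPKM and 1714 ± 38.7 in newly formed cells, and Cnp and Mobp differed by 0.60 and 1.09 without passing, as did Ermn at 120.01 ± 7.97 and 61.4 ± 54.8 FPKM. Ndrg1 was at 254 ± 44.9 FPKM (log2 difference 2.33, SE 0.26, adjusted p = 1.91e-04). Ppp1r14a was at 255 ± 29.9, Adssl1 at 69.3 ± 3.52, and Trp53inp2 at 988 ± 329 FPKM. Efhd1, Gng13 and Phospho1 completed the 10 largest differences. Newly formed cells were next-highest for 78.6% of the 98 genes. The count became 257 after median-of-ratios scaling, 58 with libraries brought to a common sum, 56 without replicate 1 of this type and 6 at a log2 difference of at least 2. The Mbp call was lost with a pseudocount of 0.1, with no filter, or without newly formed replicate 1 or myelinating replicate 1, and those of Gng13, Mal and Opalin were each lost under at least 1 alternative. Median-of-ratios scaling called Cnp, Mobp and Ermn. Mobp was also called without whole cortex replicate 2. Without newly formed replicate 1 the log2 difference of Ermn was 2.35.

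Microglia were marked by C1qa, a chain of the first complement component, at 3929 ± 1239.7 FPKM against 95.00 ± 32.2 in precursors (log2 difference 5.36, SE 0.38, adjusted p = 2.54e-08). Tmem119, a membrane protein of resident microglia, was at 879.9 ± 372 against 20.5 ± 8.87 FPKM (log2 difference 5.35, SE 0.32, adjusted p = 3.65e-09). Csf1r was at 2982 ± 678 against 104 ± 47.8 FPKM (log2 difference 4.90, SE 0.39, adjusted p = 8.83e-08). All 12 microglia markers were higher in microglia than in each other type, also adjusted over the list alone (camera adjusted p = 5.58e-11, and adjusted p = 0.262 with an estimated correlation). C1qb, C1qc, Trem2, Fcrls, Cx3cr1, Aif1, Itgam and P2ry12 had log2 differences from 2.48 to 5.06, with precursors the next type for each. Gpr84, a fatty acid receptor, was at 186 ± 45.6 FPKM (log2 difference 6.15, SE 0.20, adjusted p = 3.26e-11). Tnf, a cytokine, was at 531 ± 47.6 against 6.56 ± 0.653 FPKM in endothelial cells (log2 difference 6.14, SE 0.42, adjusted p = 1.81e-08). The chemokines Ccl3 and Ccl4 were at 2435 ± 1021 and 2769 ± 769 FPKM, with log2 differences of 6.07 and 5.81. Cd83, Gdf15 and Ncf1 were at 1834 ± 142, 767 ± 335 and 398 ± 6.12 FPKM. The paralogs Bcl2a1a, Bcl2a1b and Bcl2a1d, which short reads separate poorly, had log2 differences of 5.68, 5.80 and 6.13.

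Of 19 complement and phagocytosis genes 16 were higher and 2 lower in microglia than in the mean of the other types, and 15 were higher than in each of them (camera adjusted p = 8.27e-10, and adjusted p = 0.311 with an estimated correlation). Of 12 cytokine genes tested 12 were higher against the mean, and 10 higher than in each type, 11 adjusted over the list alone (camera adjusted p = 2.95e-09, and adjusted p = 0.251 with an estimated correlation). Il1a, an interleukin, was at 269.8 ± 207 FPKM in microglia and 58.1 ± 11.1 in whole cortex. Of 18 immediate-early and stress genes 9 were highest in microglia, among them Atf3, Egr2, Junb and Socs3. Markers of blood-derived and perivascular macrophages moved with this group: 7 of 8 tested were higher in microglia than in each other type, with Pf4 at 94.2 and 78.00 FPKM and Mrc1 at 26.9 and 12.1 FPKM in the 2 libraries. Cd79a, a B cell gene and the only lymphocyte marker tested, stood at 1.41 and 1.88 FPKM. Precursors were next-highest for 47.9% of the 985 genes. The count was 511 at a log2 difference of at least 2.

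Endothelial cells were marked by Cldn5 at 3395 ± 223 FPKM against 10.97 ± 0.463 in astrocytes (log2 difference 8.15, SE 0.57, adjusted p = 2.07e-08). Ly6c1, which has the close paralog Ly6c2, was at 996 ± 41.3 against 10.1 ± 11.1 FPKM in microglia (log2 difference 6.99, SE 0.61, adjusted p = 2.81e-07). Esam, an adhesion molecule, was at 466 ± 3.30 against 2.63 ± 0.0627 FPKM in astrocytes (log2 difference 7.01, SE 0.40, adjusted p = 1.95e-09). All 12 endothelial markers passed, also adjusted over the list alone (camera adjusted p = 2.17e-09, and adjusted p = 0.262 with an estimated correlation). The receptors Flt1, Kdr, Tek and Tie1 were at 209.9 ± 4.42, 268 ± 20.2, 119 ± 6.24 and 254 ± 2.51 FPKM, and Itm2a, Cdh5, Slco1a4, Abcb1a and Pecam1 had log2 differences from 4.98 to 6.58. Apold1, an early response gene of vessels, was at 746 ± 57.8 FPKM (log2 difference 7.39, SE 0.37, adjusted p = 4.15e-10). Car4, a carbonic anhydrase, was at 602 ± 45.2, Ctla2a at 641 ± 13.1, Eltd1 at 369.9 ± 9.48, Slc38a5, an amino acid transporter, at 379.8 ± 29.8, AU021092 at 299 ± 32.4 and Icam2 at 216 ± 13.3 FPKM.

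Of 16 genes of the blood-brain barrier 16 were higher in endothelial cells than in the mean of the other types and 13 higher than in each (camera adjusted p = 3.56e-10, and adjusted p = 0.112 with an estimated correlation). Slco1c1, a thyroid hormone transporter, was at 1267 ± 13.3 FPKM with astrocytes at 408 ± 128, and Lsr, a tricellular junction protein, at 176 ± 0.0516 FPKM. Of 20 matrix genes 12 were higher and 6 lower against the mean (camera adjusted p = 0.0103, and adjusted p = 0.419 with an estimated correlation). Fn1, Col4a1 and Col4a2, of the basement membrane, were at 291 ± 33.5, 407 ± 36.05 and 308 ± 25.5 FPKM, whereas Bcan was at 1.66 ± 0.0130 FPKM against 805 ± 101 in astrocytes. Apcdd1, Lef1, Notum and Sox17 of the Notch and Wnt targets were highest in endothelial cells. Some mural cell markers moved with this group, since 5 of 10 tested were higher than in each other type, with Rgs5 at 185 and 204 FPKM and Kcnj8 at 19.4 and 31.98 FPKM. Pdgfrb and Notch3 of that list did not. Pdgfrb was at 12.4 and 16.8 FPKM in endothelial cells and 28.2 and 20.7 in astrocytes. Notch3 was at 4.02 and 4.80 against 32.6 and 35.6 FPKM. Ttr, a choroid plexus gene, stood at 39.9 and 26.98 FPKM, and Hbb-b1 at 606 and 749 FPKM in the 2 libraries. Astrocytes were next-highest for 30.2% of the 881 genes, and 412 genes remained at a log2 difference of at least 2.

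The oligodendrocyte lineage was tested as the mean of its 3 stages against each of the other 4 types. Sox10, a transcription factor of the lineage, was at 145 ± 25.3 FPKM in precursors, 131 ± 1.60 in newly formed and 102 ± 13.8 in myelinating cells against 3.28 ± 1.78 in neurons (log2 difference 4.93, SE 0.19, adjusted p = 1.11e-10). Cldn11, a tight junction protein of myelin, was at 9.20 ± 0.126, 2154 ± 287 and 3355 ± 188 FPKM in the same order against 1.86 ± 0.142 in microglia (log2 difference 7.19, SE 0.16, adjusted p = 6.98e-13). Of 6 lineage markers 5 passed, also adjusted over the list alone (camera adjusted p = 6.67e-07, and adjusted p = 0.133 with an estimated correlation), with Olig1, Sox8, Nkx2-2 and Zfp488 at log2 differences from 1.35 to 2.93. Olig2 was at 58.5 ± 12.9 FPKM in astrocytes and 57.9 ± 9.69 in myelinating cells, with a difference under 1 (log2 difference 0.94, SE 0.19, adjusted p = 0.00366), which was 1.16 and called without astrocyte replicate 2. The largest differences included those of Cldn11, Ugt8a, Fa2h, Mog, Mobp, Bcas1, Mbp, Gsn and Gpr17, from 5.51 to 7.19. Of 20 myelin sheath genes 19 were among the 312. Lum and Ptgds of the fibroblast list were also among them. Lum was at 9.27 and 11.4 FPKM in the precursor libraries and at most 0.102 in the newly formed and myelinating libraries. The mean of the 3 stages can thus admit a gene of a single stage. The count was 118 at a log2 difference of at least 2.

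**Figure D3:**
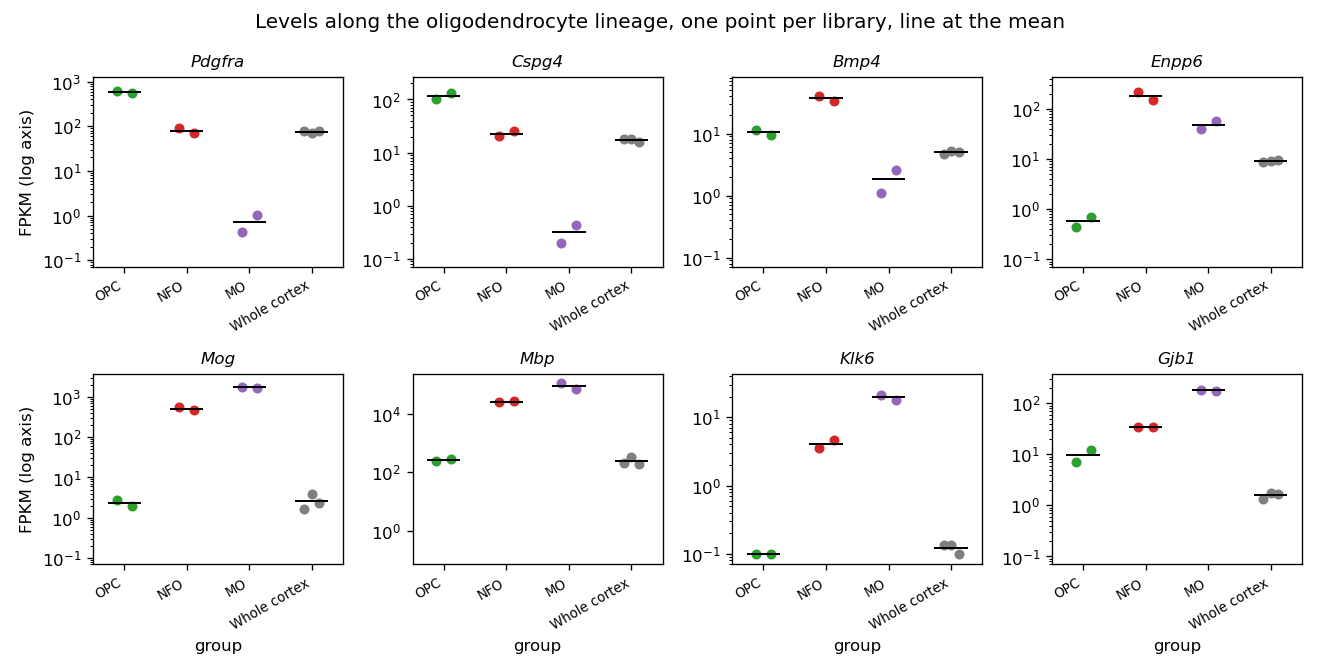
Levels of 8 genes (FPKM, log axis) in precursors, newly formed and myelinating oligodendrocytes and whole cortex (horizontal axis), with a point per library and a line at the mean. Pdgfra and Cspg4 are highest in precursors, Bmp4 and Enpp6 in newly formed cells, and Mog, Mbp, Klk6 and Gjb1 in myelinating cells.

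From precursors to newly formed oligodendrocytes the myelin genes rose most. Mag, a myelin adhesion protein, rose from 4.87 ± 0.416 to 1714 ± 38.7 FPKM (log2 difference 8.19, SE 0.27, adjusted p = 8.31e-11), Cldn11 from 9.20 ± 0.126 to 2154 ± 287 FPKM (log2 difference 7.72, SE 0.20, adjusted p = 1.72e-11), and Enpp6 from 0.579 ± 0.181 to 182 ± 44.4 FPKM (log2 difference 6.84, SE 0.21, adjusted p = 6.39e-11). Mal, Mog, Mobp and Mbp rose by 6.63 to 7.27 on the log2 scale. The myelin list had 20 of 20 genes higher, also adjusted over the list alone (camera adjusted p = 1.73e-35, and adjusted p = 0.0654 with an estimated correlation). Of 18 cholesterol synthesis genes tested 15 were higher and 0 lower (camera adjusted p = 3.16e-16, and adjusted p = 0.121 with an estimated correlation), with Lss at 11.1 ± 0.755 and 54.1 ± 6.88 FPKM, Ebp at 10.2 ± 0.547 and 45.1 ± 3.27, and Mvd at 17.5 ± 6.34 and 67.8 ± 7.35. Of 23 proliferation genes 0 were higher and 21 lower (camera adjusted p = 8.62e-08, and adjusted p = 0.392 with an estimated correlation), with Top2a, a topoisomerase of dividing cells, falling from 11.2 ± 2.74 to 0.864 ± 0.408 FPKM (log2 difference -2.71, SE 0.35, adjusted p = 2.52e-05), and Mcm6, Ccna2 and Mcm5 at log2 differences of -2.67, -2.65 and -2.52.

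The largest falls at this step were those of genes known from other cells. Igf2, a growth factor of the meninges, fell from 46.1 ± 3.71 to 0.290 ± 0.0661 FPKM (log2 difference -5.19, SE 0.52, adjusted p = 2.46e-06), Dcn from 29.5 ± 7.49 to 0.205 ± 0.148 (log2 difference -4.65, SE 0.20, adjusted p = 8.59e-10), and Col1a2 and Vtn had log2 differences of -4.78 and -4.82. Ccl4, a microglial chemokine, was at 56.4 ± 43.5 and 0.862 ± 0.115 FPKM. The hemoglobin genes Hba-a2, Beta-s and Hbb-b1 had log2 differences of -6.65 (SE 1.56), -6.26 (SE 1.33) and -5.74 (SE 1.22), whose adjusted p of 0.00289, 0.00143 and 0.00145 became 0.104, 0.123 and 0.121 when only the 2 groups were fitted. With the replicate number as a block in that fit, chosen after the values were seen, the 3 genes passed at adjusted p = 0.0171 in limma. That fit leaves very little to estimate the spread. Most genes named at this step share that adjusted p, so it does not set the hemoglobin genes apart. Across genes 736 were higher and 2582 lower, with a median log2 difference of -0.35 over all genes tested. The higher share was 22.2%, and 30.4% after median-of-ratios scaling. At a log2 difference of at least 2 the counts were 289 and 498, and with a pseudocount of 0.1 the lower count was 3962.

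From newly formed to myelinating oligodendrocytes Gjb1 rose from 33.96 ± 0.269 to 179 ± 3.98 FPKM (log2 difference 2.37, SE 0.19, adjusted p = 7.18e-07) and Ndrg1, a protein of myelinating glia, from 50.2 ± 13.9 to 254 ± 44.9 FPKM (log2 difference 2.33, SE 0.26, adjusted p = 1.26e-05). Pdgfra fell from 79.4 ± 13.6 to 0.723 ± 0.432 FPKM (log2 difference -5.56, SE 0.45, adjusted p = 7.80e-07), and C1ql1, Vcan, Cacng4, Ptprz1, Tnr, Sdc3 and 3110035E14Rik had log2 differences from -5.18 to -4.45. The myelin list had 10 genes higher and 1 lower of 20 (camera adjusted p = 5.67e-11, and adjusted p = 0.242 with an estimated correlation), with Trf, transferrin, at 413 ± 11.9 and 1906 ± 26.7 FPKM, Mal at 758 ± 369 and 2561 ± 148, and Nfasc, a protein of the node, lower at 725 ± 144 and 177 ± 19.5 FPKM. Of 18 cholesterol genes 0 changed (median 0.13), while the list ranked above other genes, whose median was lower (camera adjusted p = 7.57e-04, and adjusted p = 0.419 with an estimated correlation). Hsd17b7, Fdps and Mvk were among the largest differences in that list, from -0.68 to 0.54.

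Genes of other cells moved with this step too. Slc17a7, Camk2a, a kinase of excitatory synapses, and Nrgn, a calmodulin-binding protein of dendrites, were at 23.4 ± 22.2, 46.8 ± 46.3 and 72.1 ± 52.7 FPKM in myelinating cells, with log2 differences of 2.47 (SE 0.65), 2.36 (SE 0.67) and 2.48 (SE 0.49). Mlc1, an astrocyte protein, was at 1.41 ± 0.0611 and 13.5 ± 11.5 FPKM, and Beta-s and Hbb-b1 had log2 differences of 3.97 (SE 1.33) and 3.59 (SE 1.22). Without myelinating replicate 2 the calls of Slc17a7, Camk2a, Beta-s and Hbb-b1 were lost, at log2 differences of 1.37, 1.15, 2.77 and 2.52. Those of Slc17a7 and Camk2a were also lost without newly formed replicate 1, and those of Beta-s and Hbb-b1 without newly formed replicate 2 or with no filter. With only the 2 groups fitted the calls of all 6 genes were lost, with adjusted p = 0.104 for Nrgn and 0.119 for Mlc1, and Ptprz1, Tnr and Sdc3 lost theirs at adjusted p from 0.0501 to 0.0523. The step had 299 genes higher and 2794 lower with a median of -0.38 over all genes, a higher share of 9.67%. Median-of-ratios scaling gave 812 and 1330, a higher share of 37.9%, and a common sum gave 192 and 3598. Mbp alone filled 34.8% and 25.1% of the sum in the myelinating libraries. A pseudocount of 0.1 gave 519 and 4554. With only the 2 groups fitted the counts were 85 and 778, and at a log2 difference of at least 2 they were 21 and 418.

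Astrocytes and neurons were compared directly. Daam2, a Wnt signalling protein, was at 186 ± 59.4 FPKM in astrocytes and 3.55 ± 1.66 in neurons (log2 difference 5.37, SE 0.30, adjusted p = 2.43e-09). Bhlhe40, a transcription factor, was at 389.9 ± 26.8 and 10.2 ± 3.08 FPKM (log2 difference 5.15, SE 0.21, adjusted p = 1.40e-10), and Npy at 0.695 ± 0.647 and 646 ± 54.9 FPKM (log2 difference -8.63, SE 0.42, adjusted p = 6.81e-10). Hes1, Slco1c1, Slc39a12, Atp13a4, Sparcl1 and Gja1 were also higher in astrocytes, by 4.96 to 5.14 on the log2 scale. Reln, Sst, Snhg11, Pcp4, Basp1 and Cxcl12 had log2 differences from -8.40 to -6.95. In all 2200 genes were higher in astrocytes and 2597 higher in neurons, and 801 and 1099 at a log2 difference of at least 2.

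Of 18 glycolysis genes 3 were higher in astrocytes and 6 in neurons, a list that did not differ (camera adjusted p = 0.274, and adjusted p = 0.822 with an estimated correlation). Aldoc, an aldolase, was at 508 ± 85.7 FPKM in astrocytes and 28.1 ± 16.1 in neurons (log2 difference 4.24, SE 0.37, adjusted p = 1.92e-07). Pfkfb3, a regulator of glycolytic flux, was at 59.9 ± 15.5 and 5.26 ± 0.0225, and Hk2 at 4.43 ± 0.969 and 0.392 ± 0.165 FPKM, while Eno2, the neuronal enolase, was at 4.99 ± 0.159 and 82.2 ± 0.734 FPKM (log2 difference -3.80, SE 0.18, adjusted p = 5.42e-10). Of 15 genes of the tricarboxylic acid cycle 0 were called on either side (camera adjusted p = 0.878, and adjusted p = 0.979 with an estimated correlation), with Mdh2, Sdhb, Cs and Fh1 at log2 differences of -0.93, -0.66, 0.59 and 0.50. Of 19 RNA-binding and splicing genes 3 were higher in astrocytes and 12 in neurons (camera adjusted p = 9.10e-04, and adjusted p = 0.428 with an estimated correlation). Celf4 was at 1.06 ± 0.467 and 121 ± 20.6 FPKM (log2 difference -5.90, SE 0.33, adjusted p = 2.30e-09), and Elavl3, Celf5 and Elavl2, also RNA-binding proteins, had log2 differences of -4.65, -4.61 and -4.23.

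Isoform use was compared between astrocytes and neurons as each isoform's share of its gene. Bin1, a membrane-bending protein, used NM_001083334 for 95.4% ± 0.448 of its FPKM in astrocytes and 2.52% ± 0.151 in neurons (adjusted p = 1.30e-17), with whole cortex between at 51.5% ± 2.64. Cadm2, an adhesion molecule, used NM_001145977 for 99.7% ± 0.0142 in astrocytes and 0.643% ± 0.0836 in neurons (adjusted p = 5.60e-10), and Atp6v0a1, a proton pump subunit, used NM_016920 for 1.99% ± 2.34 and 92.99% ± 0.197. The other large differences were in C230096C10Rik, at 0.565% ± 0.0730 and 93.8% ± 5.46, Dctn1, a dynactin subunit, at 96.8% ± 2.22 and 5.25% ± 2.26, Clec16a at 98.5% ± 0.129 and 7.85% ± 9.69, Dtnb at 4.29% ± 0.788 and 94.2% ± 2.47, Herc4 at 98.8% ± 0.470 and 12.04% ± 9.42, Eif4g1 at 93.2% ± 1.81 and 8.09% ± 0.0265, and Bscl2 at 88.2% ± 10.02 and 6.99% ± 0.570. Of 1269 genes tested 543 differed by adjusted p and 354 of them by at least 20 points, with 465 at 10 points and 153 at 40. Requiring a gene sum of 20 FPKM left 69 of 241 genes.

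Of 15 genes fixed in advance, 8 could be tested and 6 differed, the same number adjusted over the list alone. Clta, a clathrin light chain, used NM_001080384 for 80.4% ± 1.51 in astrocytes and 1.69% ± 0.534 in neurons, Mtap4, a microtubule protein, used NM_001205331 for 4.59% ± 2.36 and 73.98% ± 3.92, and App, the amyloid precursor, used NM_007471 for 33.7% ± 4.498 in astrocytes, 98.4% ± 0.0284 in neurons and 6.82% ± 0.0998 in endothelial cells. Cadm1 was at 81.4% ± 3.65 and 11.02% ± 0.618, Ank2 at 8.03% ± 0.590 and 52.9% ± 6.85 (adjusted p = 3.71e-04), and Ndrg2 at 8.73% ± 0.557 and 35.3% ± 9.55, the last short of 20 points without neuron replicate 1. Mapt did not differ (adjusted p = 0.438). Pkm2, Snap25, Cltb, Dnm1 and Ktn1 have a single isoform in the files. Ank3 and Nfasc were too low in astrocytes to test, with mean sums of 0.909 and 4.82 FPKM there against 24.2 and 45.2 in neurons. Across the 21 pairs of types the share of tested genes that differed ran from 3.79% for newly formed against myelinating oligodendrocytes to 37.4% for neurons against microglia, with a median of 22.3%.

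**Figure D4:**
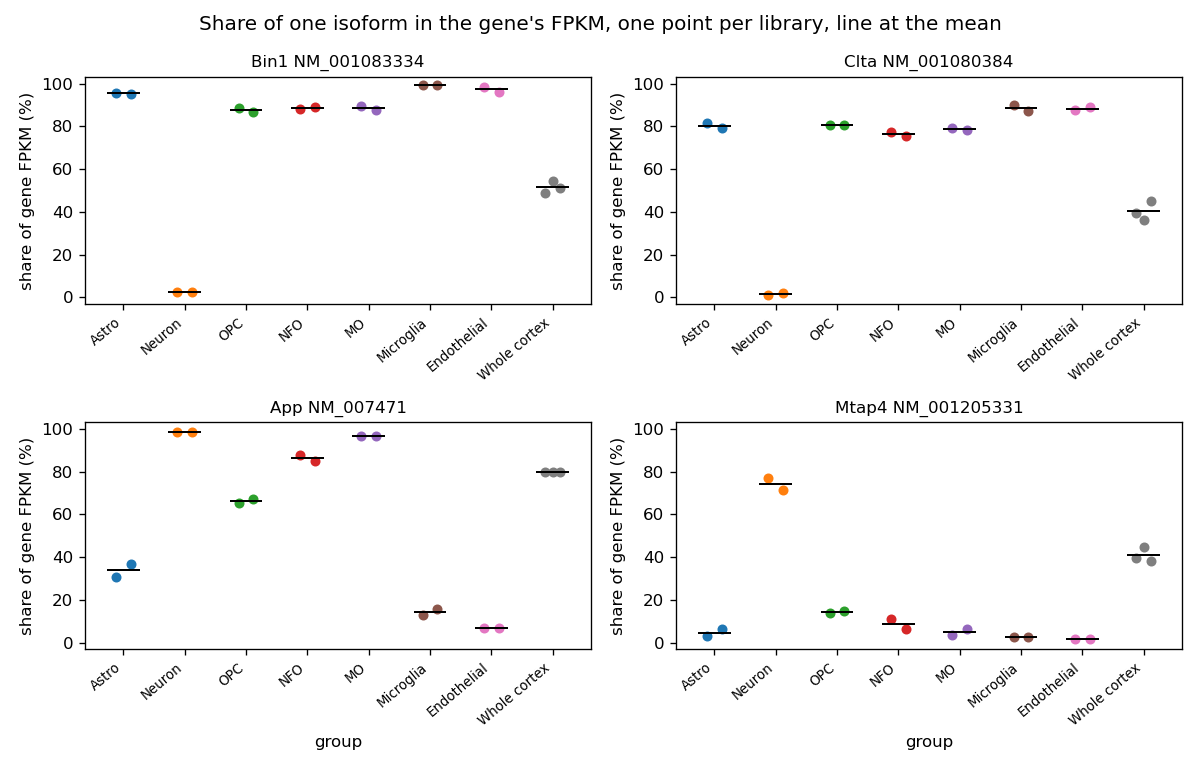
Share of an isoform in its gene's FPKM (percent, vertical axis from 0 to 100) for Bin1, Clta, App and Mtap4 in the 8 groups (horizontal axis), with a point per library and a line at the mean. Astrocytes and neurons lie far apart for each of the 4 genes.

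Whole cortex was compared with every purified type to list genes outside the range of the purified types. The comparison does not tell RNA of cells that were not purified from other differences between unsorted and purified libraries. Apc, a Wnt pathway regulator, was at 216 ± 65.8 FPKM against 25.7 ± 2.38 in astrocytes (log2 difference 2.98, SE 0.53, adjusted p = 0.00540). Brp44l, a mitochondrial pyruvate carrier, was at 31.4 ± 2.42 against 3.74 ± 0.234 FPKM in myelinating cells (log2 difference 2.77, SE 0.17, adjusted p = 5.34e-07). Ube2v1, a ubiquitin conjugating factor, was at 51.6 ± 5.82 against 7.19 ± 0.303 in microglia (log2 difference 2.68, SE 0.24, adjusted p = 1.53e-05). 4933409K07Rik was at 15.5 ± 0.953 FPKM with a log2 difference of 3.31, and Fam177a at 7.03 ± 0.181 FPKM, with the floor in all 14 purified libraries. Fam81a, Kcnj4, Crym, Kcnh3 and Tpt1p, a pseudogene, had log2 differences from 1.91 to 2.24. There were 83 such genes, 6 of them at a log2 difference of at least 2, and 40 of the 83 kept their call with a pseudocount of 0.1. Kcnh3 (log2 difference 1.96, SE 0.48, adjusted p = 0.0490) lost its call under most alternatives, Crym and Tpt1p lost theirs with a pseudocount of 0.1 (adjusted p = 0.0591 and 0.249), and Crym, Tpt1p and Apc each without at least 1 library.

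Genes lower in whole cortex than in each purified type numbered 4. A mixture of the purified types would not lie under each of them, and the source of this difference was not tested. Snhg3, which hosts small nucleolar RNAs, was at 0.233 ± 0.155 FPKM against 7.56 ± 2.89 in myelinating cells (log2 difference -2.76, SE 0.23, adjusted p = 4.22e-05), and Snhg8 at 4.43 ± 0.867 against 15.4 ± 2.35 (log2 difference -1.60, SE 0.17, adjusted p = 3.75e-04). 1810058I24Rik and 2610001J05Rik had log2 differences of -2.36 and -1.39. The count was 7 with a pseudocount of 0.1 and 2 at a log2 difference of at least 2.

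Some neuronal genes were among the 83. Of 12 neuron markers Mtap2, Nefl and Nefm were higher in whole cortex than in each purified type, 4 genes adjusted over the list alone. Of 10 genes of late neurons tested only Nrgn was higher than in each purified type, and 6 were higher than in the mean of the purified types, most of which are not neurons (camera adjusted p = 0.0481, and adjusted p = 0.524 with an estimated correlation). Nrgn was at 306 ± 75.8 FPKM in whole cortex against 35.1 ± 1.11 in neurons, Camk2a at 120.4 ± 50.8 against 10.3 ± 0.177, Snap25 at 99.8 ± 6.75 against 148 ± 43.9 and Cck at 50.1 ± 2.75 against 69.5 ± 3.57 FPKM. Of 10 genes of early neurons 10 were higher than in that mean (camera adjusted p = 3.99e-05, and adjusted p = 0.313 with an estimated correlation) and 0 higher than in each purified type. Stmn2 was at 398 ± 18.8 against 388 ± 107 FPKM in neurons, Tubb3 at 278 ± 19.9 against 331 ± 59.02, Dpysl3 at 169 ± 4.72 against 162 ± 16.6 and Dcx at 47.1 ± 3.57 against 55.7 ± 9.56 FPKM. Fezf2 and Neurod6 of the layer genes and Ccdc153 and Tmem212 of the ependymal genes were also highest in whole cortex. Of 18 immediate-early and stress genes 3 were higher and 2 lower, and the median of 0.32 and the direction of the test, which was down, differ in sign (camera adjusted p = 0.142, and adjusted p = 0.681 with an estimated correlation). The paralogs Hspa1a and Hspa1b, heat shock proteins, were at 4.29 ± 0.999 and 2.83 ± 0.440 FPKM against 783 ± 366 and 652 ± 338 in microglia, and Egr1 and Egr2 were higher by 1.11 and 1.54 on the log2 scale.

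**Figure D5:**
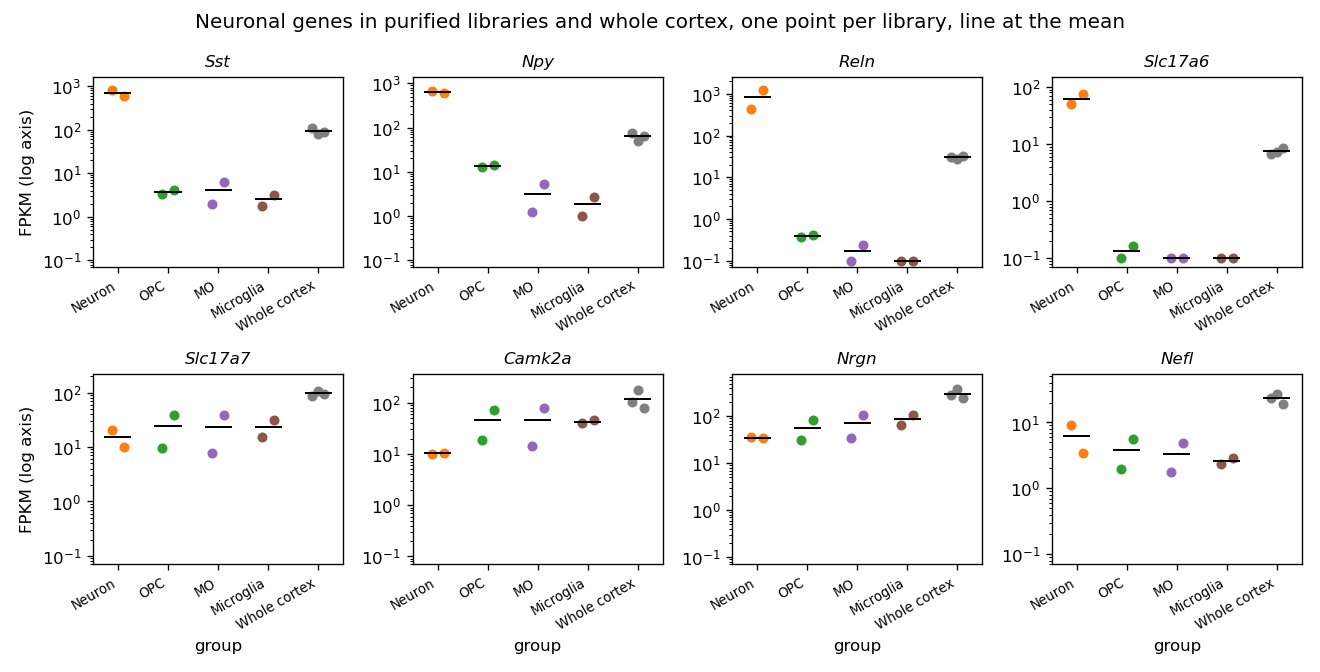
Levels of 8 neuronal genes (FPKM, log axis) in neurons, precursors, myelinating oligodendrocytes, microglia and whole cortex (horizontal axis), with a point per library and a line at the mean. Sst, Npy, Reln and Slc17a6 are highest in neurons, and Slc17a7, Camk2a, Nrgn and Nefl in whole cortex.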

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

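Leaving out both precursor replicate 1, for its hemoglobin and astrocyte RNA, and myelinating replicate 2, for its neuron RNA, was chosen after the data were seen. So was a replicate block in a fit of precursors and newly formed cells alone, and every other alternative was planned. Precursor replicate 2, which was kept, held more Slc17a7, Camk2a, Nrgn, Col1a1 and Col1a2 than replicate 1. Camk2a was at 72.9 against 18.7 FPKM. Of 227 named results 174 kept their direction and their side of the threshold under every setting that was run on them. Leaving out precursor replicate 1 and myelinating replicate 2 together was run on the counts alone. Of their values under these settings, 5339 were the same, 126 were weaker, 15 stronger and 8 reversed. The weaker ones came mostly from leaving out a library (62) and from a log2 difference of at least 2 (26). Of the counts of genes 404 stayed within 1.5 times and 33 did not, and the cause was not tested except where the alternative itself sets it. At a log2 difference of at least 2 the counts fall by construction, to 159 for astrocytes, 268 for neurons, 33 for precursors, 12 for newly formed and 6 for myelinating oligodendrocytes, 511 for microglia, 412 for endothelial cells and 118 for the lineage. The same limit left 6 genes higher and 2 lower in whole cortex, 289 and 498 for newly formed cells against precursors, 21 and 418 for myelinating against newly formed cells, and 801 and 1099 for astrocytes against neurons. With a pseudocount of 0.1 there were 7 genes lower in whole cortex, 3962 lower in newly formed cells than in precursors, and 519 higher and 4554 lower in myelinating than in newly formed cells. Median-of-ratios scaling gave 134 precursor, 42 newly formed and 257 myelinating genes, with 812 higher and 1330 lower at the last step. A common sum of FPKM gave 58 myelinating genes and 192 higher at the last step. With only the 2 groups in the fit that step had 85 higher and 778 lower. Newly formed cells against precursors and astrocytes against neurons, fitted the same way, stayed within 1.5 times. Fewer libraries to estimate the spread therefore need not account for this fall, whose cause was not tested. Of 384 list tests 212 passed with the preset correlation, 0 with the estimated correlation and 208 with a pseudocount of 0.1. Isoform differences numbered 69 with a gene sum of 20 FPKM, where fewer genes were tested, and 153 at 40 points.

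Leaving out each library in turn, where a lone library is assumed to vary like the other groups, gave 445 to 550.0 astrocyte, 703 to 836 neuron, 174 to 218 precursor, 53 to 69 newly formed, 56 to 100 myelinating, 826 to 989 microglia, 707 to 893 endothelial and 304 to 329 lineage genes. Whole cortex had 59 to 94 higher and 4 to 6 lower, and isoform differences ran from 330.0 to 362. Newly formed cells against precursors had 712 to 799 higher and 2574 to 2832 lower, myelinating against newly formed cells 230.0 to 415 and 2007 to 3411, and astrocytes against neurons 2026 to 2500.0 and 2494 to 2691. With precursor replicate 1 and myelinating replicate 2 both left out the counts were 224 for precursors, 97 for myelinating cells, and 235 higher and 3467 lower at the last step. Signs that reversed belong to genes that were not called, with adjusted p = 1 in limma. Mtap2 in neurons ran from -0.50 to 0.53 over the libraries left out, Tnr in precursors from -1.35 to 0.23, and Neu4 in newly formed cells from -0.32 to 0.0897. Median-of-ratios scaling gave -0.22 for Bcas1 and 0.0952 for Neu4, and a common sum gave -0.00905 for Mag. A block on the replicate number changed a single named call, that of Itpr2 (adjusted p = 0.105 in limma), and it gave 736 genes higher and 2579 lower in newly formed cells than in precursors. The replicate numbers were not taken as pairs, since r between the replicate differences of 2 purified groups ran from -0.25 to 0.73 with 6 of 21 over 0.1. These 6 are all the pairs among precursors, newly formed cells, microglia and endothelial cells, led by 0.73 for precursors with newly formed cells. Libraries of the same number therefore share a difference in these 4 groups. Neurons had r of -0.25, -0.24 and -0.21 with microglia, precursors and newly formed cells, a difference of opposite sign. With precursors and newly formed cells alone in the fit a replicate block gave 711 higher and 2474 lower, against 540 and 1733 without it, and it changed no named call of the main fit. Depth is unknown, so what it limits could not be measured.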

Other observations

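The tests on the neuronal genes, on the source of the fibroblast genes and on the cytokine genes were written after the values were seen, and the further fibroblast list and the relabelings before. Slc17a7, Camk2a and Nrgn of excitatory neurons stood in the microglia libraries at 154%, 413% and 246% of the neuron level, while the vesicle list stood at a median of 7.20% (0.411% to 42.4%). Carry-over from cells like those of the neuron libraries alone would put the 3 genes in the range of the vesicle list, which they exceed. The values argue against that as their only source, but the 3 genes were picked with these values known. For Slc17a7 the libraries overlap, at 15.6 and 31.4 FPKM in microglia and 20.4 and 9.99 in neurons. Against whole cortex the 3 genes stood at 24.3% to 35.3%. A first comparison with the whole vesicle list left the question of whole neurons open, since 16 of its genes lay under the lowest of the 3 and Stx1a, Vamp2 and Cplx1 reached 25.9%, 25.8% and 25.2%. The test was then rewritten for the 5 vesicle genes most abundant in whole cortex, which had a median of 7.48%, 3 of them under 0.5 of the lowest of the 3 genes. Vamp2, among the 5, stood above that lowest gene. The rewritten test and its limit were chosen with these values known, so it decides nothing, and whole neurons as a source stay open.

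Whether dendrites are carried over without cell bodies was asked with transcripts located in dendrites. A list of 11 such transcripts had a median of 34.4% of the whole cortex level in microglia against 9.46% for 19 vesicle genes (permutation p = 0.00037), and 9 of the 11 lay above the vesicle median. Of the list 4 genes had been seen before; the 7 others had a median of 34.4% (exact p = 0.00117). Mtap2 at 0.895% and Shank1 at 7.97% did not follow, and Arc at 125% and Ppp1r9b at 135% exceeded whole cortex, and these may be genes that microglia themselves express. Dlg4, at 34.4%, stood at 27.7 and 25.8 FPKM in the astrocyte libraries, so it is not a gene of neurons alone. Slc17a7 is not on the list, and genes are not independent replicates. Carry-over of dendrites would give the higher median, but expression by microglia would give it too, and the test does not tell them apart. Precursors had the vesicle list at a median of 30.2% of whole cortex and myelinating cells at 11.5%, where the 3 genes stood at 18.5% to 38.0% and 23.6% to 38.9%, and the test was not applied there.

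Fibroblast genes in the precursor libraries could come from fibroblasts among the cells or from the precursors themselves. Of 20 further fibroblast genes 7 were highest in precursors, 5 in endothelial cells, 4 in neurons, 3 in astrocytes and 1 in microglia, which does not decide it. The 6 fibroblast markers called stood in whole cortex at a median of 36.1% of the precursor level (17.1% to 53.9%), against 15.0% (6.83% to 20.7%) for the 7 precursor markers called (exact p = 0.00583). Another source of the fibroblast markers in whole cortex would give this order. Precursors as their only source are not excluded, since the ranges overlap and precursors in whole cortex may differ from the purified ones. Igf2 and Ptgds, the fibroblast markers not called, stood higher in whole cortex than in precursors. Igf2 was at 63.7, 58.2 and 63.4 FPKM in whole cortex, above every purified library. Ptgds was at 75.8 and 78.6 FPKM in newly formed cells, so precursors are not its main purified source. The exact p compares genes, which are not independent replicates. Other fibroblasts in whole cortex would leave the first question open as well.

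Cytokine genes in microglia may have been raised by the purification. If only purification raised them, they would stand lower in whole cortex, relative to microglia, than microglia markers do. The 10 cytokine genes called stood at a median of 15.5% (2.83% to 33.8%) and the 12 markers at 1.70% (0.372% to 7.84%), the opposite order (permutation p = 0.00021). For the 6 cytokines with every other type under 5% of microglia the median was 9.76%. Ccl3, Ccl4, Tgfb1 and Tnf, at 2.83%, 3.03%, 3.11% and 3.26%, lie within the range of the markers, so 4 of the 10 do not stand apart from them, and the 9 immediate-early genes had a median of 6.33% (0.433% to 14.7%). Of these, the stress genes Hspa1a and Hspa1b, at 0.548% and 0.433%, stand below the marker median, the order that a rise during purification would give. They were picked after the values were seen and lie within the range of the markers. The other immediate-early genes stand above the marker median, the lowest being Zfp36 at 4.26%. A rise in whole cortex tissue itself, or other sources there, stays open.

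Libraries were relabelled 100 times, the real grouping included. As many lineage genes as the real 312 arose in 1 of 100, the real one, with 128 the highest other. These relabelings mix cell types within groups, so the other counts are not a measure of chance alone. For genes higher and lower in whole cortex the real 83 and 4 each arose in 1 of 100 with 0 the highest other, an outcome that the mixing fixes, so chance was not tested there. Isoforms at the floor of a group and at 1 FPKM or more in the 15 other libraries numbered 13 for microglia, 10 for endothelial cells and 7 for neurons.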
